A study of Rattus norvegicus with 70 samples.

How the data were processed

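RNA was sequenced from 6 tissues of male Wistar-Kyoto rats that were exposed to air or to 0.8 ppm ozone for 4 h. Per the labels' protocols, tissues were frozen on dry ice and RNA was extracted with Qiagen kits from lung, liver, muscle and adipose tissue and with a Zymo kit from hypothalamus and adrenal gland. Messenger RNA was selected and libraries were prepared on an automated Apollo324 system, then sequenced on an Illumina NextSeq instrument, per the same protocols. The labels name 70 libraries by tissue, exposure and a number, and 68 of them had a column in the tables used here. Adrenal air 7 and muscle ozone 17 were not analysed here. The resulting groups held 6 air and 6 ozone libraries in lung, liver and hypothalamus, 5 and 6 in adrenal, 5 and 5 in adipose tissue, and 6 and 5 in muscle. The labels do not state that equal numbers in different tissues mark the same rat. Air libraries carry numbers up to 12 and ozone libraries numbers from 13. If the numbers follow an order or time of handling or collection, it cannot be told apart from ozone, also for the clock genes.

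The authors deposited 1 table of normalised gene values per tissue. Each table had 19465 gene entries, of which 24 carried a date in place of a symbol and were left out, leaving 19441. The submitters' processing notes name Partek, DESeq2 and the rn6 rat genome build, without versions or roles. The aligner, the counting method, its strand setting and the gene annotation are not given in the sources used here, so paralogs and genes that overlap on opposite strands are uncertain. No genome was used, and genes are named by the symbols in the tables. The deposited values are a signal made of gene counts divided by 1 size factor per library. This was worked out from the values: within a library every value was a whole multiple of a single step, and 100% of the values above 0 came out as whole reads within a tolerance of 0.01. Recovered totals ran from 8854272 to 18848151 reads per library. Each tissue was normalised by the authors as a separate table, so levels were compared within tissues and only fold changes were set side by side across them.

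Replicates were compared before averaging. Over genes with at least 20 reads, the lowest chi-square per degree of freedom of any pair of libraries in a group was 8.76, so no library was a copy of another of its tissue and exposure. Separate libraries carry separate numbers, but the labels do not say in words that each came from a different rat, and p-values measure the spread between these libraries.

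Genes with a mean deposited value of at least 10 in a tissue were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, using a mean-variance trend and robust variance moderation, ozone against air, each tissue apart. Adjusted p-values are Benjamini-Hochberg values from that test, and a gene with adjusted p under 0.05 is said to have risen or fallen. A fold change is on the log2(value + 1) scale, which understates the change of low genes, and is given ± its standard error. Means of deposited values are given ± SD. Differences between tissues were tested with a limma F test of the 5 tissue-by-exposure terms over the genes present in all 6 tables. That fit allows each tissue its own level but pools the spread.

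Before the data were examined, 49 gene lists were fixed from general knowledge, covering responses, metabolism, tissue functions and markers of cell types that the samples could hold. Some lists share genes, so their calls are not separate evidence. The glucocorticoid list shares Cdkn1a, Sesn1 and Ddit4 with the p53 list, Nfkbia with the inflammatory list and Per1 with the clock list. It also shares Tat and Pdk4, among others, with the fasting list, Pdk4 with the fatty acid oxidation list and Sesn1 with the muscle atrophy list. Not every shared gene is given here. Lists with at least 5 measured members were tested in each tissue with limma's camera at a preset inter-gene correlation of 0.01, and p-values were adjusted over all 269 tests of a list in a tissue. Camera with an estimated correlation is given beside each call. Of the 69 calls, 1 held with the estimated correlation, that of muscle atrophy and catabolic genes in lung. After the data were seen, a two-sided exact permutation test of the mean score of each list per library was added, adjusted over the same 269 tests. The smallest p it can give before adjustment is 0.00216 with 6 against 6 or 5 against 6 libraries and 0.00794 with 5 against 5. This test does not compare a list with other genes. It passed 71 lists, and 46 were passed by both tests. The rotation test fry, which also does not compare a list with other genes, was added too and passed 81, among them 49 of the 69 camera calls.

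Genes named in the text follow a rule set before the data were examined. It takes, in each tissue, the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 50, and up to 4 members with the lowest adjusted p of each list described. It adds 12 focal genes in every tissue, genes that moved the same way in at least 4 tissues, and the 5 genes with the lowest p in the test between tissues. Not every gene that the rule allows is named. Genes named outside it are said to have been chosen after their values were seen. Alb, Col1a1, Acta1 and Myh2, given as ranges or shares of reads, were also chosen after their values were seen. Some genes that the rule or the lists take are not reported here.

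The alternatives fixed in advance were pseudocounts of 0.5 and 10, no filter on low values, a minimum mean of 50, TMM rescaling, array weights, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered whole reads, a minimum log2 change of 1, camera with an estimated correlation, a replicate block over libraries with equal numbers (which called 4667 genes in the test between tissues) and leaving out each library in turn. On whole reads, edgeR called 2680 genes in lung, 1423 in liver, 2636 in adrenal, 203 in hypothalamus, 1033 in adipose tissue and 5651 in muscle. Alternatives added after seeing the data were fry, the exact test of list scores, muscle fits with a slow-fibre or matrix score as a covariate, adrenal without air 8 and ozone 16, and lung without air 1 and air 2. Liver without air 1 was singled out after seeing the data but is a planned fit that left out 1 library.

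The procedure was tested on simulated data. With counts drawn for the real genes and about 100 genes moved 4-fold, limma recovered 97.9% of them in lung, 94.9% in liver, 96.9% in adrenal, 94.9% in hypothalamus, 86.6% in adipose tissue and 96.9% in muscle. At 2-fold it recovered 75.8%, 57.1%, 55.6%, 73.2%, 42.9% and 59.0%, in the same order, so changes of that size were often missed. False calls made up 3.23% to 6.82% of the limma calls. In simulated lung data edgeR made 8 false calls (4.44%) and DESeq2 36 (16.8%), against 9 for limma (5.03%). In the test between tissues, 194 of 200 genes moved 4-fold were recovered, with 27 false calls. These made up a larger share of its calls than false calls did in any limma test within a tissue. A list moved in simulated lung data was called by camera, as were 2 of the 46 other lists. Counts were drawn for each gene independently, so these rates leave out variation that many genes of a library share. Error rates in the real data can be higher.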

Results

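The libraries measured messenger RNA in lung, liver, adrenal gland, hypothalamus, adipose tissue and skeletal muscle of male Wistar-Kyoto rats exposed to air or to 0.8 ppm ozone for 4 h. Wistar-Kyoto is an inbred rat strain, and ozone is an oxidant gas that reacts in the airways. The question, as the series states it, was how the transcripts of these tissues differ after ozone. Each tissue had 5 or 6 libraries per exposure, 68 in all. Recovered reads per library ran from 10714447 to 13730483 in lung, 12342650 to 16678455 in liver, 8854272 to 12769464 in adrenal, 9162216 to 13529752 in hypothalamus, 14227133 to 18848151 in adipose tissue and 14402574 to 18707084 in muscle. Genes past the threshold numbered 2623 of 14828 tested in lung (17.7%), 1440 of 12573 in liver (11.5%), 2609 of 14026 in adrenal (18.6%), 215 of 15217 in hypothalamus (1.41%), 1043 of 14252 in adipose tissue (7.32%) and 5702 of 13043 in muscle (43.7%). Median standard errors of the log2 fold change were 0.15 in lung and 0.17 in hypothalamus, 0.20 in liver and adipose tissue, 0.21 in adrenal and 0.19 in muscle. In other splits of the same libraries, camera with its preset correlation called as many as 14 to 23 lists per tissue, so each list is described by its members and set beside the exact permutation test of its score.

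**Figure D1:**
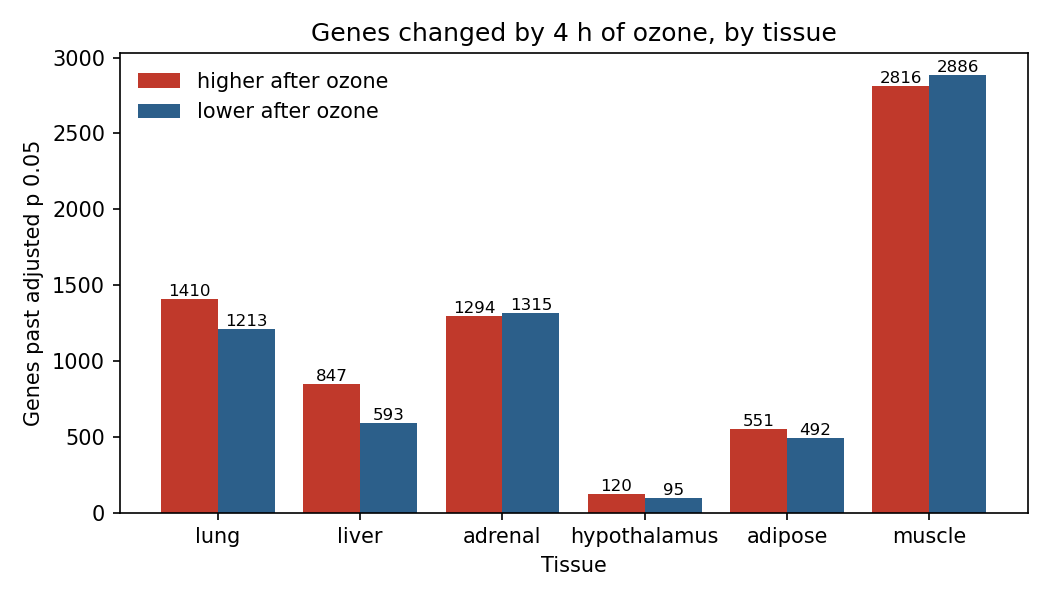
Bars give the number of genes per tissue with adjusted p under 0.05, higher (red) or lower (blue) after 4 h of ozone, from limma with 5 or 6 libraries per exposure. Muscle had the most, 2816 higher and 2886 lower, and hypothalamus the fewest, 120 and 95.

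In lung, the tissue ozone reaches directly, 25 of 34 glucocorticoid-responsive genes, 13 of 35 inflammatory mediators and the metallothionein gene Mt2A rose, and 12 of 30 T and NK lymphocyte markers and 17 of 33 interferon-stimulated genes fell. Mt2A, a metal-binding protein induced by metals and glucocorticoids, went from 41.4 ± 23.9 (SD, n = 6) in air to 996 ± 365 (SD, n = 6) after ozone, a log2 fold change of 4.64 ± 0.36 (limma adjusted p = 3.17e-06). Fkbp5, a co-chaperone of the glucocorticoid receptor and one of its standard target genes, rose from 1069 ± 674 to 7041 ± 851 (log2 fold change 2.94 ± 0.32). Cxcl2, a neutrophil-attracting chemokine, rose from 3.27 ± 1.51 to 52.8 ± 20.8 (3.66 ± 0.33), while Bank1, a B-cell adaptor protein, fell from 875 ± 131 to 282 ± 35.9 (−1.63 ± 0.12, adjusted p = 1.12e-06). For each of these genes all 6 ozone libraries lay beyond every air library. In total 1410 genes rose and 1213 fell, 254 and 202 of them by at least 2-fold.

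Of 34 measured glucocorticoid-responsive genes, 25 rose and 0 fell in lung (28 and 0 adjusted over the list alone), with a median log2 fold change of 1.11. Camera gave the list adjusted p = 7.86e-17, and adjusted p = 0.0834 with an estimated correlation. Besides Fkbp5, Tsc22d3 (1.21 ± 0.25), Per1 (1.43 ± 0.23), Sgk1 (0.54 ± 0.12) and Cebpd (1.35 ± 0.10) rose, whereas Klf9 had 0.59 ± 0.34 (adjusted p = 0.257). Zbtb16 rose by 2.99 ± 0.63 in limma (adjusted p = 0.00653) but did not pass in edgeR (adjusted p = 0.088). The list of muscle atrophy and catabolic genes, which in lung is a set of general catabolic and growth-restraining genes, had 17 risen of 31 and 0 fallen (21 and 0 adjusted over the list alone), median 0.62, camera adjusted p = 5.16e-12, and 0.0125 with an estimated correlation. Among its members were Glul, the glutamine synthetase gene (1.42 ± 0.12), and Odc1 of polyamine synthesis (1.17 ± 0.11). Among p53 target genes 9 of 23 rose and 0 fell (11 and 1 adjusted over the list alone). The median was 0.40, with camera adjusted p = 2.80e-05, and adjusted p = 0.0515 with an estimated correlation. They included the cell-cycle inhibitor Cdkn1a (2.21 ± 0.11, adjusted p = 7.75e-08), which is also in the glucocorticoid list, and Pmaip1 (0.99 ± 0.10). Circadian clock genes had 10 of 23 risen and 0 fallen (11 and 0 adjusted over the list alone). The median was 0.41, with camera adjusted p = 6.70e-05, and adjusted p = 0.0834 with an estimated correlation. Members included Bhlhe40 at 0.75 ± 0.11 and Cry2 at 0.66 ± 0.10.

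Inflammatory mediators in lung had 13 of 35 risen and 2 fallen (15 and 2 adjusted over the list alone). The median was 0.39, with camera adjusted p = 0.000581, and adjusted p = 0.54 with an estimated correlation. Cxcl1 (2.17 ± 0.27), the decoy receptor Il1r2 (1.83 ± 0.21) and the NF-kappa-B inhibitor Nfkbia (1.17 ± 0.11) rose, and the fallen members were the alarmin Il33 (−1.57 ± 0.09) and Ccl4 (−0.85 ± 0.18), the latter chosen after its values were seen. With a minimum mean of 50 the camera call was lost (adjusted p = 0.129). Immediate early and CREB target genes had 13 of 28 risen and 0 fallen (16 and 0 adjusted over the list alone). The median was 0.58, with camera adjusted p = 1.54e-06, and adjusted p = 0.516 with an estimated correlation. Sik1 rose by 1.39 ± 0.13 and Maff by 1.44 ± 0.17. Fos also rose (adjusted p = 0.00355), and Nr4a1 had 0.51 ± 0.33 (adjusted p = 0.322). Without air 10 Nr4a1 had 0.82 and passed (adjusted p = 0.00874), as it did with array weights (0.0384). In the NRF2 and antioxidant list 7 of 27 genes rose and 0 fell (9 and 1 adjusted over the list alone). The median was 0.27, with camera adjusted p = 0.0047, and adjusted p = 0.459 with an estimated correlation. Gsta1 (1.05 ± 0.10), Osgin1 (1.18 ± 0.20), Txnrd1 (0.67 ± 0.10) and the glutathione-synthesis gene Gclc (0.66 ± 0.10) rose. The haem oxygenase gene Hmox1 had 0.63 ± 0.22, not past the threshold in limma (adjusted p = 0.0601) but past it in edgeR (0.0344) and DESeq2 (0.00886) and without ozone 16 (0.0154) or ozone 19 (0.0338). Hypoxia-responsive genes had 10 of 29 risen and 2 fallen (12 and 2 adjusted over the list alone). The median was 0.21, with camera adjusted p = 0.00372, and adjusted p = 0.427 with an estimated correlation. Pfkfb3 (1.47 ± 0.11) and Hk2 (1.12 ± 0.15), genes of glycolysis, rose. Unfolded-protein and amino-acid stress genes had 10 of 34 risen and 1 fallen (10 and 1 adjusted over the list alone). The median was 0.11, with camera adjusted p = 0.0364, and adjusted p = 0.596 with an estimated correlation. Members included Atf4 at 0.62 ± 0.10. That call was lost in 2 of 12 fits that left out 1 library, with adjusted p up to 0.0671 without air 7. In the adrenal medulla and catecholamine list 7 of 18 rose and 1 fell (9 and 2 adjusted over the list alone). The median was 0.52, with camera adjusted p = 0.00574, and adjusted p = 0.242 with an estimated correlation. Members included the synaptic vesicle gene Syt1 (1.90 ± 0.15) and the neuropeptide gene Gal (4.31 ± 0.46).

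Of 30 T and NK lymphocyte markers 0 rose and 12 fell (0 and 17 adjusted over the list alone). The median was −0.64, with camera adjusted p = 8.89e-09, and adjusted p = 0.495 with an estimated correlation. The cytotoxic granule genes Gzmb (−1.37 ± 0.19) and Prf1 (−1.05 ± 0.16) and the T-cell co-receptor gene Cd8a (−1.03 ± 0.17) were among them. Of 24 B lymphocyte and plasma cell markers 0 rose and 11 fell (0 and 17 adjusted over the list alone). The median was −0.85, with camera adjusted p = 8.17e-08, and adjusted p = 0.54 with an estimated correlation. Members included Pou2af1 at −1.23 ± 0.17. Air 1 and air 2 had the highest B-cell scores. Without these libraries, the median was −0.60 for B lymphocyte and plasma cell markers in lung and −0.54 for T and NK lymphocyte markers in lung, and both lists still passed camera (adjusted p = 3.98e-06 and 7.48e-07). Interferon-stimulated genes had 1 risen and 17 fallen of 33 (1 and 21 adjusted over the list alone). The median was −0.42, with camera adjusted p = 1.44e-08, and adjusted p = 0.427 with an estimated correlation. Rsad2 (−1.13 ± 0.13), Mx2 (−1.02 ± 0.11) and Gbp5 (−0.96 ± 0.09) fell. The 1 member that rose was Cxcl10 (0.73 ± 0.23), chosen after its values were seen and called in 3 of 12 fits that left out 1 library. Neutrophil markers were not called by camera (2 of 16 rose and 6 fell, 2 and 8 adjusted over the list alone, median −0.33, adjusted p = 0.0976), with Mmp9 at −1.21 ± 0.19 and Csf3r at −0.92 ± 0.14, both chosen after their values were seen. In the exact permutation test of scores, adjusted p was 0.0157 for the glucocorticoid, inflammatory, interferon, stress, hypoxia, p53, clock, catabolic and medulla lists, 0.0233 for the NRF2, lymphocyte and neutrophil lists and 0.0364 for the immediate early list. Ciliated cell markers (0 of 22 risen and 3 fallen, 0 and 5 adjusted over the list alone, median −0.42, camera adjusted p = 0.000753, and adjusted p = 0.646 with an estimated correlation) and mitochondrially encoded genes (0 of 12 risen and 2 fallen, 0 and 2 adjusted over the list alone, median −0.27, camera adjusted p = 0.0377, and adjusted p = 0.822 with an estimated correlation) were called by camera but not by the exact test (adjusted p = 0.0935 and 0.26). Reads from mitochondrial genes made up 2.81% ± 0.648 (SD, n = 6) in air and 2.36% ± 0.174 (SD, n = 6) after ozone.

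In liver, 13 of 33 glucocorticoid-responsive genes, 13 of 35 fasting genes and 7 of 38 fatty acid oxidation genes rose, while 13 of 33 interferon-stimulated genes fell. Slc12a3, a sodium-chloride cotransporter, went from 4.76 ± 2.26 (SD, n = 6) to 238 ± 60.6 (SD, n = 6), a log2 fold change of 5.41 ± 0.26 (limma adjusted p = 5.58e-08). Cdkn1a rose from 237 ± 102 to 3108 ± 394 (3.79 ± 0.21), and the stress-responsive gene Osgin1 fell from 2846 ± 1468 to 160 ± 72.3 (−4.05 ± 0.38). Cish (−4.21 ± 0.90) and Socs2 (−3.67 ± 0.47), feedback inhibitors induced through STAT5, also fell. Altogether 847 genes rose and 593 fell, 270 and 189 by at least 2-fold.

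Glucocorticoid-responsive genes had 13 of 33 risen and 1 fallen in liver (16 and 1 adjusted over the list alone). The median was 0.60, with camera adjusted p = 7.62e-06, and adjusted p = 0.248 with an estimated correlation. Fkbp5 (2.86 ± 0.19), Tsc22d3 (1.04 ± 0.25), Per1 (1.91 ± 0.44) and the tyrosine aminotransferase gene Tat (1.80 ± 0.18) rose. Gadd45g fell (−1.27 ± 0.35, chosen after its values were seen), though it was called in only 5 of 12 fits that left out 1 library. Zbtb16 (1.82 ± 0.58, adjusted p = 0.0598), Mt2A (1.11 ± 0.34, adjusted p = 0.0516), Klf9 (0.70), Sgk1 (−0.29), Pdk4 (−0.39), Hmox1 (−0.23), Fos (0.14) and Nr4a1 (−0.05) did not pass. In limma Zbtb16 passed without air 6 or air 9 (adjusted p = 0.00315 and 0.0422), Mt2A without air 9 or ozone 19 (0.0225 and 0.0447) and Klf9 without ozone 18 (0.0174), and all 3 passed with array weights. Among gluconeogenesis and fasting genes 13 of 35 rose and 2 fell (15 and 2 adjusted over the list alone). The median was 0.32, with camera adjusted p = 4.72e-05, and adjusted p = 0.417 with an estimated correlation. Ppargc1a, a coactivator of fasting genes (2.88 ± 0.29), the aspartate aminotransferase gene Got1 (2.85 ± 0.25) and the tryptophan-degrading enzyme gene Tdo2 (2.02 ± 0.19) rose. Fatty acid oxidation and PPARA target genes had 7 of 38 risen and 1 fallen (7 and 1 adjusted over the list alone). The median was 0.22, with camera adjusted p = 0.000501, and adjusted p = 0.461 with an estimated correlation. The risen members included Pex11a (2.12 ± 0.18), Crat (1.73 ± 0.18) and the lipid-droplet gene Plin5 (1.87 ± 0.21). In the adipocyte marker list, whose risen members in liver were lipid-droplet and lipolysis genes, 5 of 12 rose and 0 fell (5 and 0 adjusted over the list alone). The median was 0.49, with camera adjusted p = 0.000611, and adjusted p = 0.0834 with an estimated correlation. They included the triglyceride lipase gene Pnpla2 (2.29 ± 0.19) and Plin4 (2.70 ± 0.37).

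The muscle atrophy and catabolic list had 9 of 30 risen and 1 fallen in liver (11 and 1 adjusted over the list alone). The median was 0.26, with camera adjusted p = 0.000511, and adjusted p = 0.234 with an estimated correlation. Foxo1, a transcription factor restrained by insulin (1.97 ± 0.25), and the autophagy gene Map1lc3b (1.90 ± 0.21) rose. Interferon-stimulated genes had 0 risen and 13 fallen of 33 (1 and 14 adjusted over the list alone). The median was −0.51, with camera adjusted p = 1.70e-07, and adjusted p = 0.461 with an estimated correlation. Members included Cxcl11 at −1.35 ± 0.19 and Rtp4 at −1.13 ± 0.17. The NRF2 and antioxidant list, in which Osgin1 and Gclm (−0.97 ± 0.19) were the 2 fallen members of 25 and 0 rose (0 risen and 2 fallen adjusted over the list alone), had median −0.14, camera adjusted p = 0.0425, and adjusted p = 0.611 with an estimated correlation. This call was lost in 5 of 12 fits that left out 1 library, with adjusted p up to 0.163 without air 2. Insulin and growth-factor signalling genes as a list were not called (3 of 31 rose, 3 fell, 3 and 3 adjusted over the list alone, adjusted p = 0.472), though Igfbp1, an insulin-suppressed binding protein gene, rose by 1.61 ± 0.22. The exact permutation test of scores gave adjusted p = 0.0157 for the glucocorticoid, fasting, fatty acid, adipocyte, catabolic and interferon lists and 0.0233 for the NRF2 list. B lymphocyte (median −0.61, camera adjusted p = 0.0314, and adjusted p = 0.647 with an estimated correlation), endothelial (−0.38, 0.0364, and adjusted p = 0.822 with an estimated correlation) and alveolar type 2 lists (−0.75, 0.0207, and adjusted p = 0.734 with an estimated correlation) passed camera alone, with 0 of 8, 0 of 20 and 2 of 13 members fallen and 0 risen, also when adjusted over the list alone. Each of these 3 lost its camera call without air 1, a library that stood apart on the first principal component (adjusted p = 0.119, 0.334 and 0.119).

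In the adrenal gland, which makes glucocorticoids in its cortex and catecholamines in its medulla, 8 of 37 catecholamine genes, 9 of 23 clock genes and 8 of 34 stress genes rose, and 12 of 32 interferon-stimulated genes and 6 of 26 cholesterol genes fell. Pkd2l1, a cation channel gene, rose from 16.2 ± 8.71 (SD, n = 5) to 1169 ± 272 (SD, n = 6), a log2 fold change of 6.21 ± 0.30 (limma adjusted p = 5.56e-07). Other high values were those of the potassium channel gene Kcnj1 (6.29 ± 0.48), Wnt9b (5.36 ± 0.35) and the protease gene Adamts4 (3.66 ± 0.46). The orphan nuclear receptor gene Nr4a3 fell from 4549 ± 3820 to 587 ± 252 (−2.66 ± 0.45), and the beta-3 adrenergic receptor gene Adrb3 fell by 3.01 ± 0.35 on the log2 scale. Overall counts were 1294 risen and 1315 fallen genes, 461 and 327 by at least 2-fold.

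Adrenal medulla and catecholamine genes had 8 of 37 risen and 0 fallen in adrenal (10 and 0 adjusted over the list alone). The median was 0.29, with camera adjusted p = 0.00384, and adjusted p = 0.495 with an estimated correlation. The receptor tyrosine kinase gene Ret (3.28 ± 0.42), the neuropeptide genes Vgf (2.42 ± 0.33), Gal (2.01 ± 0.32) and Penk (0.76 ± 0.13), and Th, the rate-limiting enzyme of catecholamine synthesis (0.99 ± 0.20), rose. Circadian clock genes had 9 of 23 risen and 1 fallen (9 and 2 adjusted over the list alone). The median was 0.37, with camera adjusted p = 0.015, and adjusted p = 0.234 with an estimated correlation. Arntl, which encodes the clock activator BMAL1 (2.43 ± 0.15), Rora (1.92 ± 0.26) and Cry2 (0.83 ± 0.14) rose. Among unfolded-protein and amino-acid stress genes 8 of 34 rose and 1 fell (10 and 1 adjusted over the list alone). The median was 0.16, with camera adjusted p = 0.0246, and adjusted p = 0.495 with an estimated correlation. Members included the endoplasmic reticulum chaperone gene Hspa5 at 0.99 ± 0.13 and Asns at 1.00 ± 0.15. Without air 8 that call was lost (adjusted p = 0.0547). Fibroblast and matrix genes had 5 of 29 risen and 0 fallen (5 and 0 adjusted over the list alone). The median was 0.25, with camera adjusted p = 0.0167, and adjusted p = 0.323 with an estimated correlation. Members included Mmp2 at 0.49 ± 0.12.

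Interferon-stimulated genes had 0 risen and 12 fallen of 32 in adrenal (0 and 18 adjusted over the list alone). The median was −0.73, with camera adjusted p = 1.21e-07, and adjusted p = 0.554 with an estimated correlation. Cxcl10 (−2.24 ± 0.36), Oasl2 (−1.51 ± 0.24) and Ddx58 (−1.34 ± 0.15) fell. Cholesterol synthesis and uptake genes had 2 of 26 risen and 6 fallen (2 and 7 adjusted over the list alone). The median was −0.28, with camera adjusted p = 0.026, and adjusted p = 0.646 with an estimated correlation. Hmgcs1 (−1.31 ± 0.22), Lss (−0.996 ± 0.15) and Hsd17b7 (−0.89 ± 0.18), enzymes of the pathway, fell. Leaving out air 9 or ozone 15 ended that call (adjusted p = 0.0945 and 0.0512). Steroidogenesis genes did not pass as a list (7 of 30 rose and 3 fell, 7 and 3 adjusted over the list alone, median 0.08, camera adjusted p = 0.584), with the lipoprotein receptor gene Scarb1 at 1.49 ± 0.31, Mrap at 0.99 ± 0.21 and Akr1b7 at 0.84 ± 0.14. Among glucocorticoid-responsive genes in adrenal 8 of 34 rose and 1 fell (8 and 2 adjusted over the list alone). The median was 0.19, with camera adjusted p = 0.0425, and adjusted p = 0.323 with an estimated correlation. Fkbp5 rose by 0.60 ± 0.14 and Tgm2 by 1.89 ± 0.13, while Per1 (0.05 ± 0.18), Klf9 (−0.04 ± 0.21) and Tsc22d3 (−0.44 ± 0.17, adjusted p = 0.102) did not pass. Mt2A fell by 0.92 ± 0.27, a call kept in 5 of 11 fits that left out 1 library. The glucocorticoid call was lost without air 2 (adjusted p = 0.0668), air 8 (0.096), air 9 (0.0517) or ozone 16 (0.0607). In the exact permutation test of scores, adjusted p was 0.0157 for the catecholamine, clock and stress lists, 0.0233 for the interferon and matrix lists, 0.0312 for the cholesterol list and 0.0873 for the glucocorticoid list. Fry passed that glucocorticoid list (adjusted p = 0.000278). Air 8 and ozone 16 stood apart on the first principal component, and without both 4220 genes were called.

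Camera also called the neuropeptide and stress-axis list in adrenal (7 of 18 rose, 7 adjusted over the list alone, median 0.41, adjusted p = 0.00825, and adjusted p = 0.54 with an estimated correlation), which shares Vgf, Gal, Penk and Th with the catecholamine list. The alveolar type 1 list had 6 of 13 risen (11 adjusted over the list alone), median 1.03, camera adjusted p = 6.70e-05, and adjusted p = 0.54 with an estimated correlation. Neither list passed the exact test (adjusted p = 0.069 for each), and fry passed both (adjusted p = 0.01465 and 0.01418). Members included Ager at 1.84 ± 0.41 and Clic5 at 0.81 ± 0.16. Bile acid and xenobiotic genes (1 of 24 risen and 1 fallen, 1 and 1 adjusted over the list alone, median −1.14, adjusted p = 0.0474, and adjusted p = 0.822 with an estimated correlation) and hepatocyte markers (0 of 24 risen and 1 fallen, 0 and 0 adjusted over the list alone, median −1.42, adjusted p = 0.0307, and adjusted p = 0.905 with an estimated correlation) were called as lower by camera, but not by the exact test (adjusted p = 0.388 and 0.481). Single adrenal libraries ranged from 39.8 to 16610 in the liver transcript Alb. Leaving out air 9 or ozone 16 left 7 adrenal lists called by camera, against 11.

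In the hypothalamus, the brain region that starts the pituitary-adrenal stress axis, 13 of 34 glucocorticoid-responsive genes rose. Mt2A rose from 149 ± 24.4 (SD, n = 6) to 942 ± 211 (SD, n = 6), a log2 fold change of 2.63 ± 0.15 (limma adjusted p = 7.82e-07). Fkbp5 rose from 677 ± 255 to 2446 ± 438 (1.90 ± 0.20), and Cdkn1a by 2.37 ± 0.20. Pla2g3, a secreted phospholipase gene (3.06 ± 0.18), and the metallothionein genes Mt1m (3.17 ± 0.37) and Mt1 (2.85 ± 0.30) had the highest values. Of the 120 risen and 95 fallen genes, 47 and 13 moved by at least 2-fold. Fallen genes included Cd180, a Toll-like receptor homologue of immune cells (−2.76 ± 0.28), and the hedgehog receptor gene Ptch1 (−1.19 ± 0.12).

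Of 34 glucocorticoid-responsive genes 13 rose and 0 fell in hypothalamus (25 and 0 adjusted over the list alone). The median was 0.69, with camera adjusted p = 8.79e-22, and adjusted p = 0.0921 with an estimated correlation. Zbtb16 (2.27 ± 0.39) and Arrdc2 (1.47 ± 0.14) were among them. Sgk1 rose by 1.27 ± 0.29 (adjusted p = 0.0451), called in 3 of 12 fits that left out 1 library, whereas Tsc22d3 (0.66, adjusted p = 0.0785), Per1 (0.77, adjusted p = 0.0548) and Fos (−0.79 ± 0.21, adjusted p = 0.0851) did not pass. Without air 3 Tsc22d3 and Per1 passed (adjusted p = 0.0282 and 0.0165), without air 1 Fos did (0.0375), and all 3 did with array weights. The adipocyte marker list had 3 of 10 risen and 0 fallen (6 and 0 adjusted over the list alone). The median was 0.41, with camera adjusted p = 3.91e-05, and adjusted p = 0.0589 with an estimated correlation. Its risen members were the lipid-droplet gene Plin4 (2.09 ± 0.27), the glycerol-3-phosphate dehydrogenase gene Gpd1 (1.78 ± 0.14) and the lipase gene Pnpla2 (1.40 ± 0.14), which are not restricted to adipocytes. Gpd1 was also the 1 risen gene of 11 in the fast muscle fibre list (1 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 0.00315, and adjusted p = 0.295 with an estimated correlation). The muscle atrophy and catabolic list had 3 of 32 risen and 0 fallen (7 and 0 adjusted over the list alone). The median was 0.21, with camera adjusted p = 2.03e-05, and adjusted p = 0.102 with an estimated correlation. Members included Sesn1 at 0.53 ± 0.09. Interferon-stimulated genes had 0 risen and 2 fallen of 31 (0 and 8 adjusted over the list alone). The median was −0.45, with camera adjusted p = 1.49e-08, and adjusted p = 0.284 with an estimated correlation. The fallen members were Gbp5 (−0.76 ± 0.16) and Mx2 (−0.48 ± 0.09), called in 5 and 9 of 12 fits that left out 1 library. Neuropeptide and stress-axis genes were not called (0 of 39 rose and 1 fell, 0 and 1 adjusted over the list alone, adjusted p = 0.172).

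Cholesterol synthesis genes had 1 of 26 risen in hypothalamus, Insig1 (0.77 ± 0.09), with 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.0174, and adjusted p = 0.54 with an estimated correlation, and without ozone 15 the call was lost (adjusted p = 0.124). Ciliated cell markers had 0 of 21 past the threshold (2 risen adjusted over the list alone). The median was 0.18, with camera adjusted p = 0.00226, and adjusted p = 0.427 with an estimated correlation. The exact permutation test of scores gave adjusted p = 0.0157 for the glucocorticoid, adipocyte, fast-fibre, catabolic and interferon lists, 0.0312 for cholesterol and 0.0364 for ciliated genes. Camera alone called 6 further lists, with estimated-correlation adjusted p between 0.495 and 0.806: matrix genes (median −0.75), smooth muscle (−0.45), endothelial (−0.34), alveolar type 1 (−0.41) and type 2 (−1.06) markers lower, and fatty acid oxidation genes (0.12) higher. Of their members, 3 fatty acid oxidation genes passed the threshold and 0 of the others did, and the exact test gave each list adjusted p of 0.107 or more. Single libraries ranged from 157 to 3821 in the matrix transcript Col1a1 after ozone and from 1118 to 2865 in air. The count of 215 genes fell to 116 without air 2, air 4 or air 7, to 128 without air 3 or ozone 14, to 141 without ozone 13 and to 105 without ozone 16. DESeq2 called 551 genes, edgeR 203 and limma with array weights 723.

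**Figure D2:**
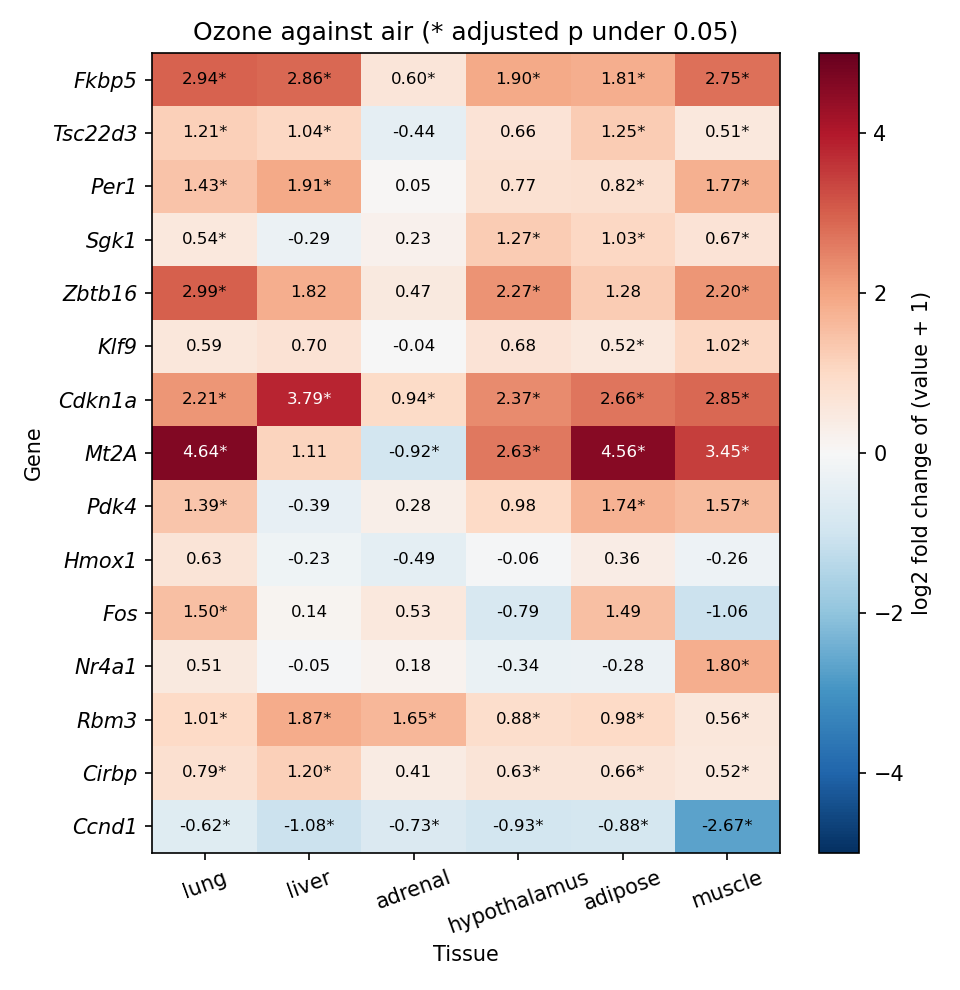
Colours and numbers give the log2 fold change of (value + 1), ozone against air, for 15 genes in 6 tissues, with an asterisk where adjusted p is under 0.05. Fkbp5, Cdkn1a and Rbm3 carry an asterisk in all 6 tissues and rose, Ccnd1 fell in all 6, and Mt2A ranged from −0.92 in adrenal to 4.64 in lung.

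In adipose tissue, 15 of 33 glucocorticoid-responsive genes, metallothionein genes among them, rose, and the adrenergic receptor genes Adrb3 and Adra1d fell. Mt2A rose by 4.56 ± 0.40, Mt1 by 4.13 ± 0.47 and Thbs1, a matrix glycoprotein gene, by 2.75 ± 0.34. Adrb3, the beta-3 adrenergic receptor gene through which catecholamines drive lipolysis, fell from 5336 ± 1165 (SD, n = 5) to 546 ± 293 (SD, n = 5; −3.50 ± 0.43), and the alpha-1D receptor gene Adra1d fell by 2.22 ± 0.25. In all, 551 genes rose and 492 fell, 217 and 151 of them by at least 2-fold.

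Glucocorticoid-responsive genes had 15 of 33 risen and 1 fallen in adipose tissue (22 and 1 adjusted over the list alone). The median was 0.87, with camera adjusted p = 9.10e-12, and adjusted p = 0.38 with an estimated correlation. Fkbp5 (1.81 ± 0.28), Tsc22d3 (1.25 ± 0.22), Sgk1 (1.03 ± 0.20), Cdkn1a (2.66 ± 0.26) and Errfi1 (1.74 ± 0.21) rose. The fallen member was Rasd1, a dexamethasone-inducible Ras-like gene (−3.48 ± 0.34). Per1 (0.82), Klf9 (0.52) and Pdk4 (1.74) also passed, but were called in 3, 6 and 4 of 10 fits that left out 1 library, and Zbtb16 (1.28, adjusted p = 0.12) and Fos (1.49 ± 1.25, adjusted p = 0.539) did not pass. The muscle atrophy and catabolic list had 7 of 32 risen and 1 fallen (10 and 1 adjusted over the list alone). The median was 0.35, with camera adjusted p = 8.11e-05, and adjusted p = 0.349 with an estimated correlation. Members included Foxo1 at 1.26 ± 0.18. The exact permutation test of scores gave adjusted p = 0.0356 for both lists.

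Lipolysis, storage and adipokine genes moved both ways in adipose tissue: 3 of 35 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.532), with the lipid-droplet gene Cidec at 1.43 ± 0.18. Among insulin and growth-factor signalling genes 1 of 32 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.606), and the insulin receptor substrates Irs1 (−1.53 ± 0.24) and Irs2 (−1.001 ± 0.17) were among the fallen. Camera alone called 6 lists. Interferon-stimulated genes had 0 risen and 4 fallen of 33 (0 and 11 adjusted over the list alone), median −0.60, adjusted p = 1.72e-06, and adjusted p = 0.646 with an estimated correlation, and the exact permutation test gave adjusted p = 0.181. Unfolded-protein and amino-acid stress genes had 4 of 33 risen and 0 fallen (4 and 0 adjusted over the list alone), median 0.16, adjusted p = 0.0155, and adjusted p = 0.647 with an estimated correlation. Members included the folate-cycle gene Mthfd2 at 1.88 and Atf4 at 0.87. Immediate early genes had 4 of 29 risen and 0 fallen (4 and 0 adjusted over the list alone), median 0.40, adjusted p = 0.0167, and adjusted p = 0.734 with an estimated correlation, lost without ozone 22 (adjusted p = 0.423). T and NK markers (median −0.32, 0 members past the threshold), matrix genes (0.25, 1 member) and fast-fibre genes (−1.70, 0 members) had adjusted p = 0.633, 0.646 and 0.895 with an estimated correlation, and the muscle transcript Acta1 ranged from 110 to 33920 between adipose libraries. Without air 5, 6 or 9 the count of 1043 genes fell to 609, 638 or 634, and without ozone 19 or 23 to 622 or 655. DESeq2 called 1616 genes and edgeR 1033.

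In skeletal muscle, 24 of 32 atrophy genes, 25 of 33 glucocorticoid-responsive genes and 17 of 18 fast-fibre genes rose, while 16 of 18 slow-fibre genes, 24 of 29 matrix genes and 15 of 24 inflammatory mediators fell. Ddit4, an inhibitor of mTOR signalling, rose from 267 ± 112 (SD, n = 6) to 4401 ± 1153 (SD, n = 5), a log2 fold change of 4.12 ± 0.30 (limma adjusted p = 2.13e-06). The amino acid transporter gene Slc7a8 rose by 3.66 ± 0.17 (adjusted p = 2.07e-08), Mical2 by 4.56 ± 0.37 and the bone- and muscle-secreted factor gene Ostn by 4.99 ± 0.54. Myl2, the slow-fibre myosin light chain gene, fell from 3590 ± 1936 to 447 ± 682 (−4.26 ± 0.86, adjusted p = 0.00181), with 4 of 5 ozone libraries below every air library. The 2816 risen and 2886 fallen genes included 724 and 1347 that moved by at least 2-fold.

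Muscle atrophy and catabolic genes had 24 of 32 risen and 2 fallen in muscle (25 and 2 adjusted over the list alone). The median was 1.46, with camera adjusted p = 8.89e-09, and adjusted p = 0.284 with an estimated correlation. Foxo1 (2.98 ± 0.15, adjusted p = 3.30e-08), the muscle ubiquitin ligase gene Trim63 (2.29 ± 0.17) and Fbxo31 (1.70) rose. Glucocorticoid-responsive genes had 25 of 33 risen and 1 fallen (25 and 1 adjusted over the list alone). The median was 1.57, with camera adjusted p = 1.49e-09, and adjusted p = 0.349 with an estimated correlation. Fkbp5 (2.75 ± 0.35), Mt2A (3.45 ± 0.47), Zbtb16 (2.20 ± 0.17), Per1 (1.77 ± 0.24), Klf9 (1.02 ± 0.13), Pdk4 (1.57 ± 0.27) and Sgk1 (0.67 ± 0.18) rose, and the fallen member was the phosphatase gene Dusp1 (−1.16 ± 0.32), chosen after its values were seen. Tsc22d3 passed in limma (0.51 ± 0.19, adjusted p = 0.039) but in neither edgeR nor DESeq2. Gluconeogenesis and fasting genes had 8 of 20 risen and 3 fallen (8 and 3 adjusted over the list alone). The median was 0.35, with camera adjusted p = 0.0486, and adjusted p = 0.516 with an estimated correlation. Members included Ppp1r3c at 3.02 ± 0.21. This call was kept in 5 of 11 fits that left out 1 library, with adjusted p up to 0.0762 without air 2.

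Fast fibre genes had 17 of 18 risen and 0 fallen (18 and 0 adjusted over the list alone). The median was 1.32, with camera adjusted p = 3.30e-08, and adjusted p = 0.554 with an estimated correlation. Members included Mybpc2 at 1.99 and Tnnc2 at 1.68. Slow fibre genes had 0 of 18 risen and 16 fallen (0 and 17 adjusted over the list alone). The median was −2.97, with camera adjusted p = 1.85e-05, and adjusted p = 0.646 with an estimated correlation. Members included Tpm3 at −3.64 ± 0.81 and Myoz2 at −3.45. The slow-fibre score differed widely between the 5 ozone libraries, from −0.45 in ozone 23 to −4.26 in ozone 24, where the air mean is 0. The fast myosin gene Myh2 took 7.43% ± 1.73 (SD, n = 6) of the reads in air and 16.4% ± 2.66 (SD, n = 5) after ozone, and mitochondrial genes took 13.2% ± 1.81 and 9.82% ± 2.36. Fibroblast and matrix genes had 0 of 29 risen and 24 fallen (0 and 26 adjusted over the list alone). The median was −1.33, with camera adjusted p = 1.90e-07, and adjusted p = 0.646 with an estimated correlation. Members included the proteoglycan genes Dcn at −2.22 and Lum at −1.73. Oligodendrocyte markers, which in muscle are largely genes of myelinating nerve, had 6 of 7 fallen and 1 risen (6 and 1 adjusted over the list alone). The median was −1.90, with camera adjusted p = 0.0307, and adjusted p = 0.54 with an estimated correlation. Mal (−2.30) fell and Aspa rose (2.71 ± 0.17), and with a minimum mean of 50 the call was lost (adjusted p = 0.0567).

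**Figure D3:**
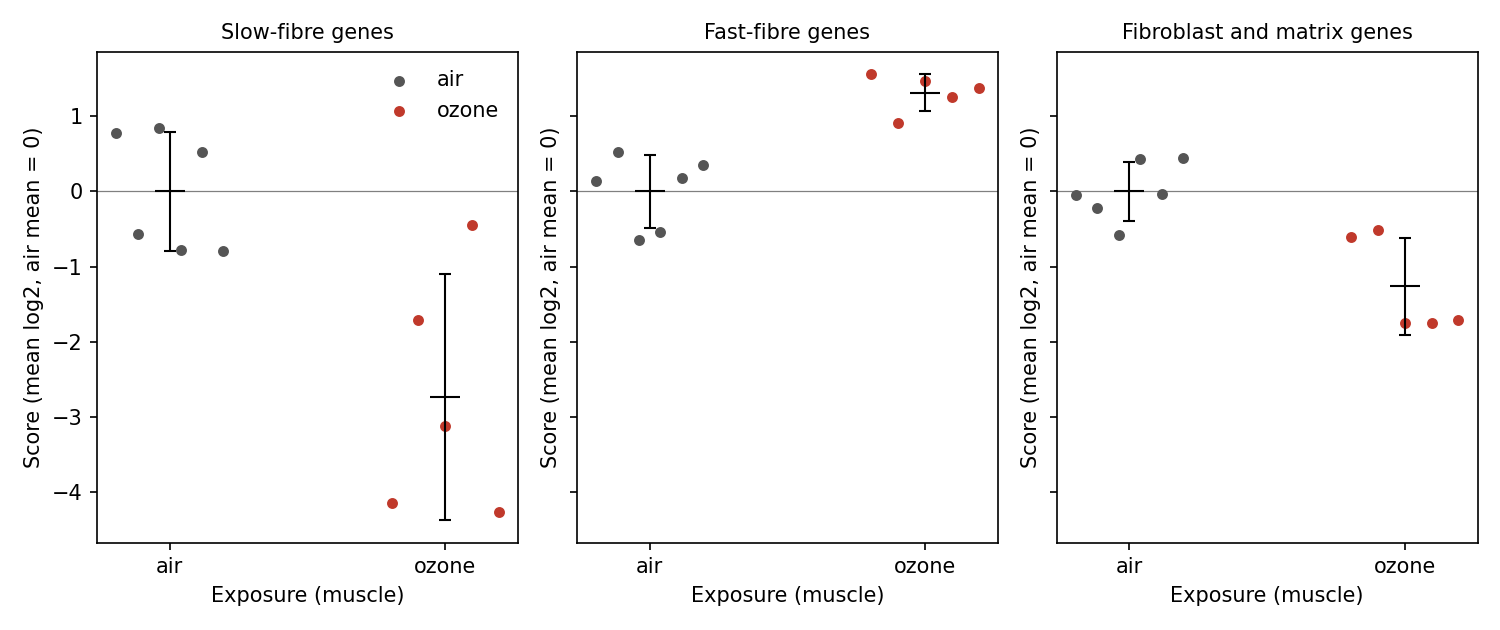
Points are muscle libraries (6 air in grey, 5 ozone in red), bars the mean and SD of each exposure, and the axis is the mean log2 value of a gene list with the air mean set to 0. Slow-fibre scores after ozone ran from −4.26 to −0.45, fast-fibre scores from 0.92 to 1.56 and matrix scores from −1.75 to −0.51.

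Inflammatory mediators fell in muscle, 15 of 24 with 1 risen (16 and 1 adjusted over the list alone). The median was −1.03, with camera adjusted p = 0.00159, and adjusted p = 0.646 with an estimated correlation. The alarmin gene Il33 (−2.13), the endothelial adhesion genes Selp (−2.94) and Icam1 (−1.56) and the growth factor gene Csf1 (−1.40) fell, and Nfkbia rose (0.70 ± 0.25, chosen after its values were seen, called in 5 of 11 fits that left out 1 library). Interferon-stimulated genes had 15 of 31 fallen and 0 risen (18 and 1 adjusted over the list alone). The median was −0.66, with camera adjusted p = 1.48e-05, and adjusted p = 0.54 with an estimated correlation. Members included Gbp2 at −1.80 and Oasl2 at −1.47. Endothelial markers had 10 of 22 fallen and 3 risen (10 and 3 adjusted over the list alone). The median was −0.42, with camera adjusted p = 0.0361, and adjusted p = 0.652 with an estimated correlation, and Kdr, the VEGF receptor gene, fell by 0.99. Smooth muscle and pericyte markers had 10 of 18 fallen and 0 risen (12 and 1 adjusted over the list alone). The median was −0.43, with camera adjusted p = 0.0334, and adjusted p = 0.495 with an estimated correlation. Members included Acta2 at −1.51. These 2 camera calls were lost in 4 and 2 of 11 fits that left out 1 library, with adjusted p up to 0.0751 without ozone 13 and 0.0604 without air 2. The exact permutation test of scores gave adjusted p = 0.0157 for the glucocorticoid, catabolic, fast-fibre, inflammatory, interferon and oligodendrocyte lists, 0.0233 for the fasting, endothelial and smooth muscle lists, 0.0312 for matrix and 0.0364 for slow-fibre genes. Monocyte and macrophage markers passed camera alone (6 of 18 fallen, 3 adjusted over the list alone, median −0.67, adjusted p = 0.015, and adjusted p = 0.785 with an estimated correlation). With the slow-fibre score or the matrix score as a covariate, both added after seeing the data, 1749 and 644 genes were called in place of 5702.

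Across tissues, 11111 genes were present in all 6 tables, and 368 rose and 316 fell in at least 3 tissues, where independent lists of the same lengths would give 90.2 and 58.5. In all 6 tissues 5 genes rose and 1 fell. Fkbp5 had log2 fold changes of 2.94 in lung, 2.86 in liver, 0.60 in adrenal, 1.90 in hypothalamus, 1.81 in adipose tissue and 2.75 in muscle, and Cdkn1a had 2.21, 3.79, 0.94, 2.37, 2.66 and 2.85 in the same order. The cold-inducible RNA-binding protein gene Rbm3 rose by 1.01, 1.87, 1.65, 0.88, 0.98 and 0.56, though in muscle it was called in 3 of 11 fits that left out 1 library and in neither edgeR nor DESeq2. Fv1 and the transfer-RNA methylation gene Trmt6 completed the risen genes, but the call of Fv1 in hypothalamus was kept in 3 of 12 such fits and that of Trmt6 in adipose tissue in 3 of 10. Ccnd1, which encodes the cell-cycle activator cyclin D1, was the 1 gene that fell in all 6 (−0.62, −1.08, −0.73, −0.93, −0.88 and −2.67). The clock gene Arntl rose in 5 tissues, from 0.70 in lung to 2.43 in adrenal, and had 0.30 ± 0.10 in hypothalamus (adjusted p = 0.19). Aspa, which cleaves N-acetylaspartate, rose in 5 tissues, by 1.43 to 2.71, and had 0.41 ± 0.26 in adrenal (adjusted p = 0.314). Cd180 fell in 5 tissues, from −0.98 in lung to −2.76 in hypothalamus, with −0.27 ± 0.19 in adrenal (adjusted p = 0.367). Its liver and adipose calls were kept in 10 of 12 and 9 of 10 fits that left out 1 library.

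Overlaps of calls between tissues were above those of independent lists in each of the 15 pairs and both directions by Fisher's exact test, adjusted over 30 tests. Lung and liver shared 250 risen genes where 80.6 would come from independent lists, and lung and adipose tissue shared 216 where 51.8 would. The overlap nearest to independence was that of genes fallen in adrenal and muscle, 294 against 264 (adjusted p = 0.0305). In that pair 416 other genes moved in opposite directions. No number from independent lists was worked out for these, so the count does not by itself show opposed responses. Whether rats contributed to several tissues is not stated in the labels, so the tissues may not be independent samples.

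The size of the ozone effect differed between tissues for 4654 of 11111 genes (41.9%) in the limma F test. Lowest p-values belonged to Slc7a8, Txndc5, Dcaf13, Nectin1 and Il33. Il33 fell in lung (−1.57), liver (−1.07) and muscle (−2.13) and rose in adrenal (2.30 ± 0.14). Slc7a8 rose by 3.66 in muscle, 0.51 in lung and 0.69 in adipose tissue, the last kept in 4 of 10 fits that left out 1 library. Txndc5, an endoplasmic reticulum disulfide isomerase gene, rose by 2.47 ± 0.20 in adrenal and fell by 0.49 in muscle. The nucleolar gene Dcaf13 rose by 2.07 in liver, 1.23 in adipose tissue and 0.36 in lung, the last called in 4 of 12 fits that left out 1 library and not with edgeR (adjusted p = 0.0601). Nectin1, a cell adhesion gene, rose by 2.10 ± 0.16 in adrenal and 0.60 in lung and fell by 0.78 in liver and 1.67 in muscle. For the median of the glucocorticoid list, the values were 1.11 in lung, 0.60 in liver, 0.19 in adrenal, 0.69 in hypothalamus, 0.87 in adipose tissue and 1.57 in muscle, a difference between tissues that was not tested for the list as a whole. Interferon-stimulated genes had medians between −0.73 and −0.42 in the 6 tissues, and the exact permutation test of their scores passed in all but adipose tissue.

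**Figure D4:**
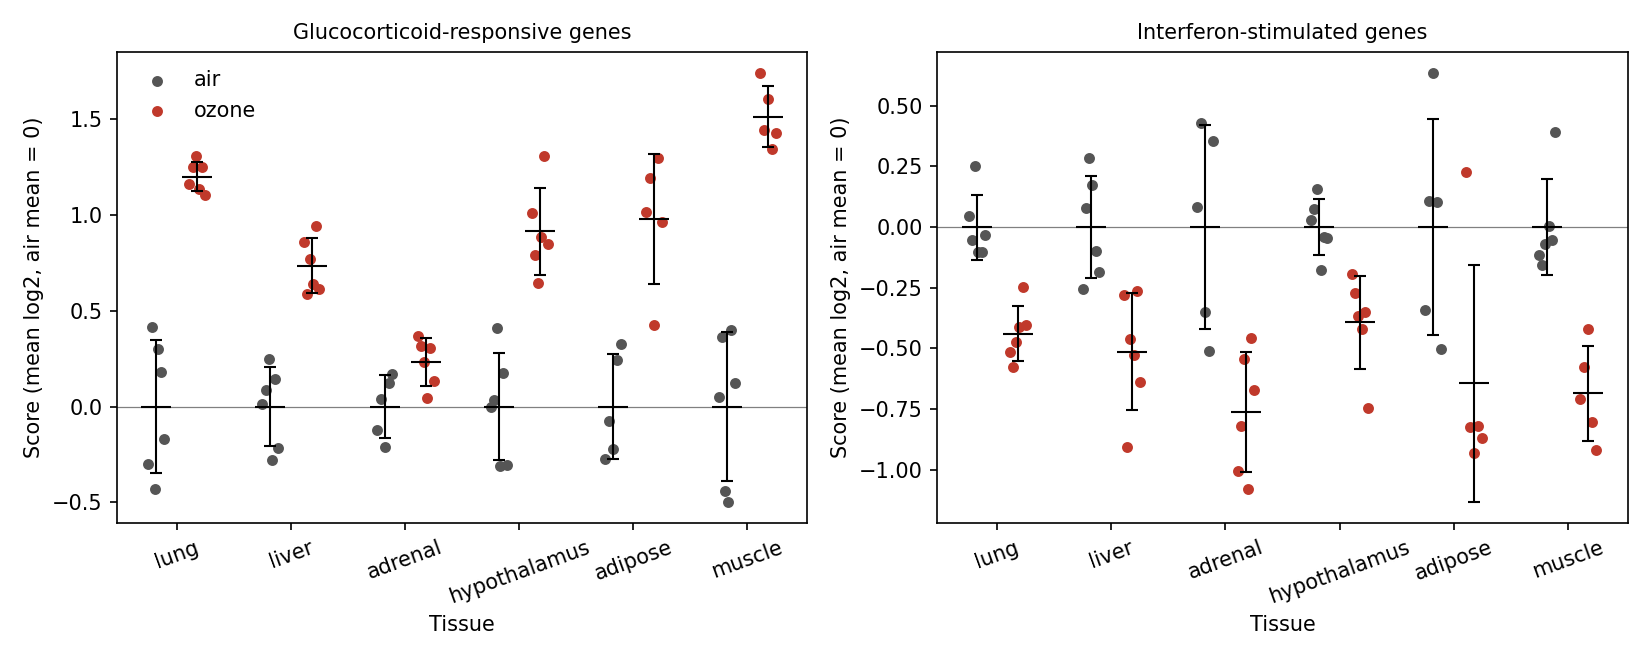
Points are libraries (air grey, ozone red), bars the mean and SD of 5 or 6 libraries, and the axis is the mean log2 value of the list's genes with each tissue's air mean set to 0. Left, glucocorticoid-responsive genes; right, interferon-stimulated genes, whose scores after ozone were below every air library in all 6 ozone libraries of lung, liver and hypothalamus, 5 of 6 in adrenal, 4 of 5 in adipose tissue and 5 of 5 in muscle.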

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

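The tests chosen after the result was seen were those of slow muscle share as the whole cause of the matrix, nerve and glucocorticoid changes in muscle, of leukocytes and single libraries behind the interferon-stimulated genes, and of lymphoid tissue and blood cells behind the lymphocyte markers in lung.

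Single libraries stood far from the rest of their group by Dixon's criterion in 23 of 222 groups (10.4%), where normally distributed values would give about 1 in 20. Deposited values were tested without a log transform, and each flagged library lay at the high end of its group. The groups also reuse the same libraries, so the excess does not by itself mark faulty libraries. In lung, air 9 had a deposited value of 1823 for Zbtb16 against at most 271 in the other air libraries, and air 10 had 221.8 for Fos and 2106 for Nr4a1. In liver air, library 9 had 604.8 for Fkbp5 and 9.137 for Slc12a3, library 6 had 769.2 for Zbtb16, library 1 had 426.8 for Cdkn1a and library 2 had 128.2 for Nr4a1. Liver ozone 16 had 2907 for Fkbp5 and ozone 13 had 69.5 for Fos. Adrenal air 8 had 566.9 for Sgk1, and adrenal ozone 16 had 2023 for Tsc22d3 and 1083 for Nr4a3. Hypothalamus air 3 had 1169 for Fkbp5, and in hypothalamus air 1 the most abundant gene took 2.691% of the reads. Adipose air 12 had 2155 for Per1, adipose air 5 had 2110 for Fos, and adipose ozone 22 had 6444 for Fos and 974.2 for Nr4a1. Adipose ozone 16 had an interferon-stimulated gene score of 0.2274, where the other ozone libraries were at −0.82 or lower. Muscle air 9 had 2181 for Fkbp5, muscle air 11 had an interferon score of 0.3911, and muscle ozone 23 had 1638 for Myl2.

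The ozone effect differed between tissues for 4654 genes in the limma F test of the tissue-by-exposure terms. Of the 12 focal genes 10 were among them, with adjusted p of 3.164e-13 for Mt2A, 1.018e-07 for Cdkn1a, 6.73e-06 for Fkbp5, 0.0001402 for Tsc22d3, 0.0007156 for Sgk1, 0.001316 for Per1, 0.008514 for Pdk4, 0.01537 for Nr4a1, 0.02653 for Hmox1 and 0.03419 for Zbtb16.

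In muscle, slow-fibre, matrix and nerve genes were lower and fast-fibre genes higher after ozone, and the pieces may have held different shares of slow muscle. Suppose that share were the whole cause of the matrix and nerve falls, and log2 values followed the slow-fibre score in a straight line. Those 35 genes would then have a median slope of 0.495 on the score within the exposure groups. The slope was −0.09371 (permutation SD 0.155), which argues against that share as their whole cause only under this assumption. The straight line was not tested, so the share is not excluded. The glucocorticoid list kept a median log2 fold change of 1.397 with the slow-fibre score as a covariate (median standard error of single genes 0.43). Of its 33 genes 21 passed the threshold, against 25, so the score as measured does not account for the whole rise. The score differed by −2.74 between the exposures and only approximates the share. This fit therefore cannot exclude the share as the whole cause. With the matrix score as a covariate the median was 1.26 (median standard error 0.44, against 0.27 without a covariate) and 14 genes passed. Many calls were thus lost as the standard errors grew and the median shrank from 1.57. Across 13007 genes outside the fibre lists the correlation between the within-group slope on the score and the fall after ozone was 0.1213, while permuted scores reached 0.602 (p = 0.35), so with 11 libraries to set the slope this test decides nothing. It held no fibre gene, and for the fibre genes a share difference cannot be told apart from a change within fibres. An effect of ozone on the fibres also stays open, as does the part of the muscle the pieces came from, which is not given in the sources used here.

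Interferon-stimulated genes had a negative median in all 6 tissues, and fewer leukocytes after ozone are a candidate explanation. The list fell further than leukocyte markers, with an exact permutation p under the 0.05 threshold, in 2 of 6 tissues, so for all tissues together this cannot be told apart from lower interferon signalling: in lung and muscle both scores fell about alike, by differences of 0.013 and 0.033. In adrenal the difference of scores was −0.7853 (exact p = 0.00216) and leukocyte markers were at 0.02. This argues against an equal fall of all leukocytes as the cause there. The other tissue was hypothalamus, with a difference of −0.2975 (exact p = 0.0195) and leukocyte markers at −0.09. These values argue against such a fall there as well. The leukocyte score pools markers of T and NK cells, B cells, macrophages and neutrophils. Fewer cells of a single kind therefore stay open in both tissues. In liver and adipose tissue the differences were −0.2236 and −0.572 (exact p = 0.232 and 0.135). A single air library with high values cannot be the cause, because the highest median of the list over all left-out libraries was −0.3493. Lower interferon signalling after ozone stays open as a hypothesis.

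In lung, T, NK and B lymphocyte markers were lower after ozone. Extra lymphoid tissue in air 1 and air 2 as the whole cause is argued against by the B-cell median without them, −0.6026. A lower share of all blood cells as the whole cause would lower the markers of each blood cell type alike. Lymphocyte markers fell by 0.76 on the log2 scale, neutrophil markers by 0.22, and macrophage and platelet markers were at 0.11 and 0.38. The fall of lymphocyte markers exceeded each of these lists, by −0.5455, −0.8712 and −1.142 (exact permutation p = 0.00433, 0.00649 and 0.00216), and the 3 lists pooled by −0.8064 (0.00649), which argues against an equal fall of all blood cells. A smaller fall of neutrophils alongside stays open. Fewer lymphocytes in the lung after ozone and lower transcript levels per lymphocyte both stay open, and these libraries hold no cell counts.

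Other splits of the same libraries into groups of the same sizes, 100 per result with the real split included, tested whether chance can be excluded. For gene counts it can, with 1 split as large in lung (2623, highest other 196), liver (1440, highest other 1), adrenal (2609, highest other 1341) and muscle (5702, highest other 3294). For the 4654 genes that differ between tissues the highest other was 421. The other splits broke up the exposure groups in every tissue. They therefore stand for no ozone effect in any tissue, not for an equal effect in all, and decide nothing about differences between tissues. For the 684 genes shared by at least 3 tissues the highest other was 0. Most other splits called 0 genes in most tissues, so that count was bound to be near 0 and decides nothing about sharing. In hypothalamus 2 splits were as large as the real 215, the other with 638 genes, and in adipose tissue 2 were as large as the real 1043, the other with 1549. The share of 2 in 100 is low, but the other split called more genes than the real one in each tissue. Chance is therefore less firmly excluded there. How far these other splits overlap the real grouping was not examined. A structure of the hypothalamus and adipose libraries apart from exposure stays open and was not tested. High counts in other splits of adrenal and muscle leave such a structure open there as well. For the number of lists called by camera chance cannot be excluded: 20 splits gave as many as the 15 of lung (highest other 23), 41 the 10 of liver (17), 15 the 11 of adrenal (15), 14 the 13 of hypothalamus (19), 59 the 8 of adipose tissue (14) and 18 the 12 of muscle (17).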

How the results depend on the processing

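Chosen after seeing the data were the fits without adrenal air 8 and ozone 16, without lung air 1 and air 2, and with muscle covariates, besides fry and the exact test of list scores. The other settings given here were planned. The 374 gene results followed through the alternatives, of which the text names a part, kept direction and side of the threshold under pseudocounts of 0.5 and 10 and under TMM scaling. Of the 323 called among them, 286 were called in every fit that left out 1 library. Gene counts stayed within 1.5 times under both pseudocounts, both filters, TMM and edgeR. The changes below have causes that were not tested, except that a minimum log2 change removes small changes by construction. The muscle covariates widened the median standard error of the glucocorticoid genes and also shrank their median. Lost precision was not told apart from change that the covariates took up.

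With array weights 3941 genes were called in lung, 2302 in liver, 4822 in adrenal and 723 in hypothalamus, and 7534 differed between tissues (the cause was not tested). DESeq2 called 551 in hypothalamus and 1616 in adipose tissue (the cause was not tested). A minimum log2 change of 1 left 456 genes in lung, 459 in liver, 788 in adrenal, 60 in hypothalamus, 368 in adipose tissue and 2071 in muscle. With an estimated correlation camera called 1 list in lung and 0 in liver, 0 in adrenal, 0 in hypothalamus, 0 in adipose tissue and 0 in muscle. Without adrenal air 8 and ozone 16, 4220 genes were called (the cause was not tested). The slow-fibre covariate left 1749 muscle genes and the matrix covariate 644, and both covariates differ between the exposures, which widens the standard errors. With them 8 and 3 interferon-stimulated genes fell in muscle, against 15 in the main test, with list medians of −0.67 and −0.46 against −0.66.

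Leaving out 1 library at a time gave 105 to 286 genes in hypothalamus, 609 to 1224 in adipose tissue and 7 to 12 lists in adrenal. In the other tissues gene counts ran from 1972 to 3346 in lung, 1062 to 1721 in liver, 1960 to 3519 in adrenal and 4756 to 5727 in muscle.

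Reversed log2 fold changes belonged to genes near 0 or not called in the main test, with Adgre1 in muscle as the exception. With array weights, Fos in liver had −0.25, Per1 in adrenal −0.060, Klf9 in adrenal 0.041 and Dcaf13 in hypothalamus −0.0082. On whole reads, Nr4a1 in liver had 0.0060 with edgeR and 0.0054 with DESeq2, and Dcaf13 in hypothalamus −0.0055 with DESeq2. With the matrix covariate, Hmox1 in muscle had 0.52 and Adgre1 0.12. Leaving out libraries moved Fos in liver from −0.12 to 0.43, Nr4a1 in liver from −0.28 to 0.20, and in adrenal Per1 from −0.13 to 0.13, Klf9 from −0.16 to 0.10, Pdk4 from −0.069 to 0.51, Nr4a1 from −0.16 to 0.43 and Slc7a8 from −0.046 to 0.061. In hypothalamus Hmox1 moved from −0.16 to 0.11, Nectin1 from −0.025 to 0.037 and Dcaf13 from −0.059 to 0.064, and in adipose tissue Nr4a1 from −0.78 to 0.079 and Txndc5 from −0.077 to 0.047.

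Libraries of equal number were checked for pairing over 15 pairs of tissues. The 90 pairs of equal number had a mean correlation of −0.0097, from −0.516 to 0.508, and 16 (17.8%) correlated best with their own number. A replicate block gave 4667 genes that differ between tissues, including all 4654 of the fit without it. Within a tissue no number is shared between air and ozone, so no paired analysis was possible there because air and ozone libraries carry different numbers.

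In simulated adipose libraries limma recovered 42.9% of 2-fold changes.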

Other observations

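The test of body temperature and the fry tests below were chosen after the result was seen.

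The lists in this paragraph were not called by camera, though some had many members past the threshold. Of all tested genes 17.7% passed it in lung, 11.5% in liver, 1.41% in hypothalamus and 43.7% in muscle. The share of cell-cycle genes that passed in muscle was below that of all muscle genes. Hepatic acute-phase genes, which the liver induces in systemic inflammation, had 2 of 26 risen and 0 fallen in liver (2 and 0 adjusted over the list alone), median 0.05, camera adjusted p = 0.792. Cell-cycle genes had 2 of 34 risen and 10 fallen in muscle (2 and 10 adjusted over the list alone), median −0.33, camera adjusted p = 0.179. Lung monocyte and macrophage markers moved both ways, 7 of 23 risen and 4 fallen (9 and 4 adjusted over the list alone), camera adjusted p = 0.201. Neuronal activity and synapse genes in hypothalamus had 0 of 28 past the threshold (0 adjusted over the list alone), camera adjusted p = 0.532. P53 target genes in liver had 8 of 23 risen and 4 fallen (10 and 4 adjusted over the list alone), camera adjusted p = 0.0592. The rotation test fry passed the muscle cell-cycle, lung macrophage and liver p53 lists (adjusted p = 0.02315, 0.0224 and 0.0002776) and not the acute-phase and neuronal lists (0.4627 and 0.7663).

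The cold-inducible genes Rbm3 and Cirbp were higher after ozone. Rbm3 was called in all 6 tissues, and Cirbp in 5, with log2 fold changes of 0.79 in lung, 1.20 in liver, 0.63 in hypothalamus, 0.66 in adipose tissue and 0.52 in muscle, beside 0.41 in adrenal (adjusted p = 0.0552, and 0.0268 without air 8). The Cirbp calls in hypothalamus, adipose tissue and muscle were kept in 4 of 12, 9 of 10 and 7 of 11 fits that left out 1 library, and the Rbm3 call in muscle in 3 of 11. A lower body temperature after ozone is a candidate explanation, and it would lower heat-shock genes other than these as well. The score of the other heat-shock and chaperone genes was lower with an exact permutation p under the 0.05 threshold in 1 of 6 tissues, the adrenal (−0.32, exact p = 0.0195), with −0.13 in lung (exact p = 0.191), −0.10 in liver (0.32), −0.0003 in hypothalamus (0.998), −0.10 in adipose tissue (0.476) and −0.45 in muscle (0.13). The hypothesis stays open, since no temperature was used here and heat-shock genes respond to more than temperature.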
